A study of Homo sapiens with 28 samples.

How the data were processed

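RNA from primary human aortic endothelial cells was measured on 28 Agilent whole-genome arrays, 4 to a slide on 7 slides. Per the labels, the RNA of each treated culture was labelled with Cy5 and a pool of 6 untreated control cultures with Cy3, and only RNA of sufficient quality was used. Cultures treated for 4 h received the particles for the last 4 h of a 24 h period, per the labels. No array had the dyes swapped, so a dye effect on a gene adds to each of its ratios. The deposited array files hold, per the file headers, the raw intensity of each spot and of its local background in both channels from Feature Extraction 10.5.1.1. They also hold a processed intensity after background subtraction and dye normalization, and a log10 ratio of the treated to the control processed signal, per the file headers. The table of values deposited by the authors holds the same ratio as log2, and 100% of its values matched the log10 ratio of the files after conversion, within 6.0e-04. No pair of arrays had identical values (0 pairs), and 0 pairs correlated under -0.3. Of 10 spike-in probes the same one had the highest ratio on 28 of 28 arrays, and the same one the lowest on 28.

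Raw intensities were background corrected with normexp and an offset of 50, converted to log2 ratios and normalized within each array by loess, with limma 3.58.1 in R 4.3.3, statmod 1.5.0 and the data.table package, version 1.17.8. Each array held 45015 spots, of which 1639 were control spots and were left out, and 41000 distinct probes. A probe was kept when it lay well above background in the treated channel on all 3 arrays of a group or in the control channel on at least 14 of 28 arrays, and was measured on at least 2 arrays of each group, which left 33367 probes. Spots called outliers by the scanner software were set to missing (31 values among the genes tested). A gene with several probes (6551 of 24453) took the one of highest mean intensity. Per comparison up to 524 genes (worms at 4 h) had probes called both ways. Symbols came from the array files and RefSeq genes on GRCh38.p14, for names alone. Of all probes 25398 matched by accession, 2510 by symbol, 789 by synonym and 12303 not. Of genes tested 16095 matched and 8358 not.

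The 9 groups with 3 arrays (27 arrays) were fitted with 1 mean each in limma, with moderated variances and two-sided tests. Comparisons were each group against 0 (the pool), 6 contrasts between groups, 4 contrasts between times, and 2 interactions with time. P-values were adjusted by the Benjamini-Hochberg method within each comparison, with a threshold of 0.05. A total of 29 gene lists, markers of other cell types among them, were tested with camera at a preset correlation of 0.01, adjusted over the lists of each comparison, and again with an estimated correlation. Adjustment over the list alone used the limma p-values of its members. The groups, comparisons, gene lists, alternatives and the rule for named genes were fixed before the data were examined. By that rule, named genes were the 10 that rose most and the 10 that fell most in each comparison among those past the test and with the same sign on all arrays, or with non-overlapping values in contrasts, from which the text takes a selection. To these came up to 4 members of each gene list with the largest change among those past the test, and genes without a symbol were passed over. The 1.5 h worm array had no replicate, stayed outside the fit and is given as values.

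The same code was tested on simulated data with 24424 genes. For worms at 4 h against the pool it called 59 of 67 genes changed by a log2 of 0.5, 66 of 67 changed by 1 and 66 of 66 changed by 2, with 6 unchanged genes. For worms against spheres at equal mass these were 55, 66 and 66, with 4 unchanged genes. A shift of 0.5 given to the mitosis list was recovered at adjusted p = 3.2e-87, with 1 of 28 other lists called, and 16 comparisons left unchanged gave 0 calls in limma.

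Alternatives were the authors' processed signals, their value table, median centring, Aquantile scaling between arrays, no filter on background, an intensity trend with robust variances, and slide as a random or fixed block or within the slide that holds both groups. Others were scan run as a covariate, the replicate letter as a block, the arrays of the groups compared alone, each group minus the mean of the other 8, and each replicate left out in turn. After the data were seen, 3 were added, namely leaving out a pair of arrays that stand apart from their groups, the treated channel alone, and the control channel of the other set of arrays. The scans fell into 2 runs, with 8 and 20 arrays.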

Results

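RNA abundance was measured on 28 Agilent arrays with 2 colours each in primary human aortic endothelial cells, the cells that line the aorta. Each treated sample carried Cy5 and each control pool carried Cy3, so every value is a log2 ratio of treated cells to untreated cells of the same kind. The 9 groups of 3 arrays were silica worms at 100 µg/ml for 4 h and for 24 h, silica spheres at 100 µg/ml for 4 h, silica spheres at 73 µg/ml for 4 h and for 24 h, and the polyamidoamine dendrimers G3.5-COOH, negatively charged, and G4-NH2, positively charged, at 0.5 µM for 4 h and for 24 h. Both silica shapes were 200 nm wide and the worms about 1000 nm long. A worm sample at 1.5 h on 1 array belongs to no comparison. The median background-corrected intensity per array was 80.9 to 168 in the control channel and 147 to 237 in the treated channel, and 73.4% to 83.9% of probes lay well above background in the control channel. Ratios below are log2 ± SE with n = 3 arrays per group, and the number of arrays limits the precision. The median of a gene list is one of log2 ratios or, in contrasts, of their differences. SE and p-values rest on the spread within all 9 groups, not 1 alone. A test against the pool leaves out the controls' own spread.

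The control channel did not look alike on all arrays, although the labels describe 1 pool of 6 control samples. It fell into a set of 9 arrays, those of the worm groups at 4 h and 24 h and of the 100 µg/ml spheres, and a set of 19 arrays, all others. Correlations across genes were 0.992 to 0.999 within the first set, 0.987 to 0.999 within the second and 0.952 to 0.968 between them, and 3312 genes differed at least 2-fold between the sets (1859 higher and 1453 lower in the second). A contrast between groups of different sets therefore cannot separate the treatments from the sets, and this holds for both equal-area comparisons of shape and for the comparison of sphere doses. No slide held both groups of a contrast of shape, dose or charge, so these cannot be separated from the slide either, save at equal mass, where 1 worm array of 24 h on each slide links them. In 1 array of the worm 24 h group 2399 genes lay at least 2-fold from the control channel, against 234 and 243 in the other two, and in 1 array of the 100 µg/ml spheres 88, against 582 and 562. In the treated channel the arrays of the first set lay between -0.0395 and 0.0708 on a scale that runs from 0 at the first control set to 1 at the second, save that array at 0.835, and those of the second set between 0.843 and 0.998.

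**Figure D1:**
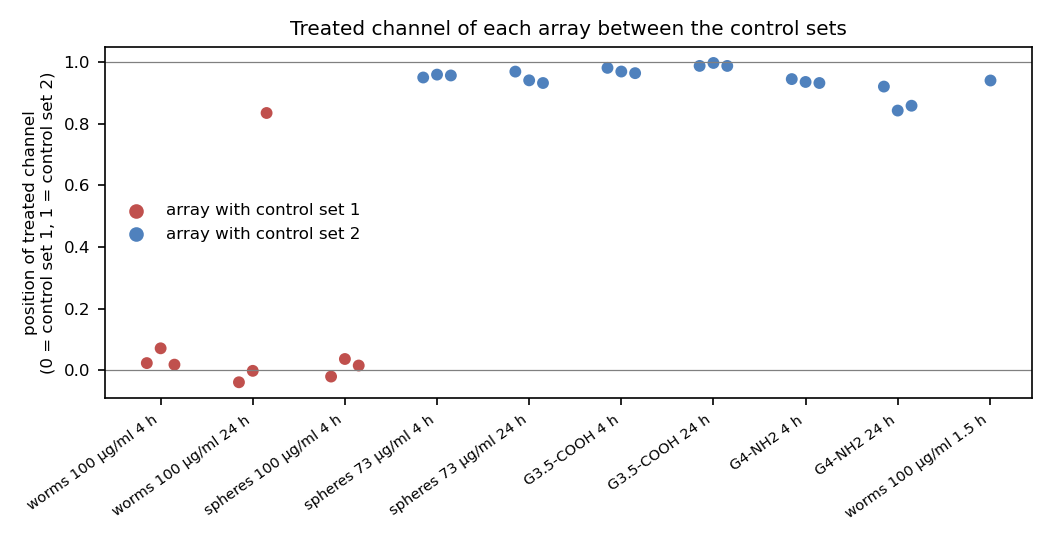
Position of the treated channel of each array between the control sets, where 0 is the mean of the first set and 1 that of the second, over 3312 genes. Points are arrays, and 1 point of the worm 24 h group lies at 0.835 while the other arrays of the first set lie at 0.0708 or lower.

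Against the control pool, with loess normalization, each silica group had more changed genes than the negatively charged dendrimer. Of 24453 genes tested, 10632 changed with worms at 4 h and 10556 at 24 h, 9345 with 100 µg/ml spheres, and 9027 and 10147 with 73 µg/ml spheres at 4 h and 24 h. G3.5-COOH changed 1610 genes at 4 h and 761 at 24 h, and G4-NH2 changed 7579 and 7620. Changes of at least 2-fold were fewer, with 347 genes higher and 188 lower for worms at 4 h. The share of changed genes that were higher was 46.9% for worms at 4 h, 50.2% at 24 h, 47.7% for 100 µg/ml spheres, 51.1% and 53.6% for 73 µg/ml spheres, 65.8% for G3.5-COOH at 24 h and 52.6% and 53.1% for G4-NH2. Centring each array on its median in place of the loess curve gave 60.5%, 70.9%, 61.5%, 62.6% and 75%, 79.6%, and 71.3% and 73.5% in the same order. That centring moved the median over all genes by -0.10 to 0.17 and by more than 0.1 in 5 comparisons. The order of the groups turned with it, to 15524 genes for G3.5-COOH at 4 h against 5168 and 5285 for 73 µg/ml spheres, and with each group fitted alone, to 5086 for G3.5-COOH and 42 for worms at 24 h. Without both arrays that stand apart, named above, G3.5-COOH had 5039 and 3708 genes and G4-NH2 11494 and 11549.

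The first question was what silica worms did to the cells within 4 h. SELE, which encodes E-selectin, the adhesion molecule that slows leukocytes on activated endothelium, rose by 4.70 ± 0.10, and the stress-induced transcription factor ATF3 by 4.42 ± 0.07. The neutrophil chemokine CXCL2 (3.46 ± 0.08), the AP-1 subunits FOS (3.43 ± 0.08) and FOSB (3.26 ± 0.09), the nuclear receptor NR4A1 (2.99 ± 0.12) and the small GTPase RRAD (2.88 ± 0.10) also rose, while ANKK1 (-2.09 ± 0.13), ALPK1 (-1.99 ± 0.12) and SLITRK2 (-1.95 ± 0.14) fell. Of the inflammatory activation genes, 24 of 26 rose and 2 did not pass (24 rose adjusted over the list alone), with CXCL3 (2.59 ± 0.13) and BIRC3 (2.47 ± 0.08), an apoptosis inhibitor induced by NF-kB, among them. The inflammatory activation median was 1.25 (adjusted p = 6.2e-24). Immediate early genes moved with them, as 18 of 20 rose and 2 did not pass (18 rose adjusted over the list alone). Their median was 1.45 (adjusted p = 3.5e-19). Of the AhR targets, which serve xenobiotic metabolism, 5 of 5 rose (5 rose adjusted over the list alone), with TIPARP (0.61 ± 0.04). The AhR target median was 0.52 (adjusted p = 0.0041). Among ribosomal proteins 26 of 36 rose and 10 did not pass (28 rose adjusted over the list alone), and on the authors' processed signals their adjusted p was 0.21. The ribosomal protein median was 0.30 (adjusted p = 2.1e-08, adjusted p = 0.051 with an estimated correlation). TMED9 and AKT2 were also among the 10 that rose most (3.55 ± 0.52 and 2.78 ± 0.38), but the second control set minus the first stood at 2.96 and 2.75. In limma each named gene was past adjusted p = 9.3e-06, and 3 of the 9 lists past the camera test held with an estimated correlation. Against the control channel of the other set the direction of the inflammatory and immediate early lists held (medians 2.14 and 1.73), whereas TMED9 (0.60) and AKT2 (0.03) were not past the test.

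After 24 h with worms the question was which responses persisted or arose. SELE stood at 5.60 ± 0.10 and RRAD at 4.20 ± 0.10, followed by BIRC3 (4.01 ± 0.08), the chemokine CCL20 (4.00 ± 0.07), ATF3 (3.93 ± 0.07), the cytokine-induced ubiquitin-like modifier UBD (3.53 ± 0.09) and the inflammatory cytokine TNF (2.86 ± 0.04). Inflammatory activation covered nearly the whole list, as 24 of 26 rose and 2 did not pass (25 rose adjusted over the list alone). Their median was 2.34 (adjusted p = 2.9e-32). Of the NRF2 targets of oxidative stress 16 of 22 rose, 1 fell and 5 did not pass (16 rose and 1 fell adjusted over the list alone), led by the haem-degrading enzyme HMOX1 (1.93 ± 0.12) and the autophagy receptor SQSTM1 (1.52 ± 0.08). The NRF2 target median was 0.32 (adjusted p = 1.2e-06). Interferon response genes rose too, in that 19 of 26 rose, 2 fell and 5 did not pass (20 rose and 2 fell adjusted over the list alone), with the antiviral GTPase MX1 at 1.93 ± 0.15. The interferon response median was 0.34 (adjusted p = 1.1e-07). Of the zinc-binding metallothioneins 9 of 10 rose and 1 did not pass (9 rose adjusted over the list alone). Their median was 1.01 (adjusted p = 2.0e-06, adjusted p = 0.12 with an estimated correlation), and 0.66 without replicate c. Mitosis genes went the other way, and 30 of 30 fell (30 fell adjusted over the list alone), with the kinetochore gene NUF2 at -1.41 ± 0.21 (-0.78 without replicate c). The mitosis median was -0.76 (adjusted p = 5.1e-25). DNA replication genes fell with them, as 28 of 30 fell and 2 did not pass (28 fell adjusted over the list alone), led by the thymidine kinase TK1 (-1.25 ± 0.11). The DNA replication median was -0.63 (adjusted p = 2.8e-19). Of the cholesterol synthesis genes 19 of 23 rose and 4 did not pass (19 rose adjusted over the list alone). Their median was 0.31 (adjusted p = 1.5e-08). Of the integrated stress response 19 of 24 rose and 5 did not pass (21 rose adjusted over the list alone). Their median was 0.46 (adjusted p = 1.1e-09). The control sets differed in both falling lists, so that against the other set the mitosis median was 0.12, that of DNA replication 0.01, that of the integrated stress response -0.05 and that of cholesterol synthesis 0.10, while inflammatory activation stayed at 3.04. Over all calls for this group 3600 kept and 4537 turned direction against that set. Each named gene was past adjusted p = 1.3e-05 in limma, NUF2 and TK1 turned direction against the other set, and 42 genes changed in a fit to the 3 arrays alone, in which HMOX1, SQSTM1, MX1, NUF2 and TK1 were not past the test.

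Spheres at the mass of the worms asked whether a rounder particle of the same width gives a like response at 4 h. SELE rose by 4.25 ± 0.10, ATF3 by 3.54 ± 0.07, FOSB by 2.72 ± 0.09 and NR4A1 by 2.60 ± 0.12, with the leukocyte adhesion molecule VCAM1 at 2.52 ± 0.14 and CXCL2 at 2.42 ± 0.08. Among those that fell most were SLITRK2 (-1.92 ± 0.14), ANKK1 (-1.92 ± 0.13) and the growth factor GDNF (-1.84 ± 0.30). Of the inflammatory activation genes 24 of 26 rose and 2 did not pass (24 rose adjusted over the list alone). Their median was 1.0 (adjusted p = 2.0e-24). Of the immediate early genes 16 of 20 rose and 4 did not pass (16 rose adjusted over the list alone). Their median was 0.89 (adjusted p = 2.5e-16). AhR targets shifted as a group, since 4 of 5 rose and 1 did not pass (4 rose adjusted over the list alone). Their median was 0.43 (adjusted p = 0.0037). Of the smooth muscle markers 5 of 8 fell and 3 did not pass (5 fell adjusted over the list alone), including SYNPO2 (-0.49 ± 0.07), which organizes actin. The smooth muscle marker median was -0.28 (adjusted p = 0.025, adjusted p = 0.11 with an estimated correlation). DNA replication genes fell by list, and 17 of 30 fell, 3 rose and 10 did not pass (19 fell and 3 rose adjusted over the list alone), their median turning to 0.29 when each array was centred on its median. Their median was -0.23 (adjusted p = 1.9e-04, adjusted p = 0.29 with an estimated correlation). In limma the named genes were past adjusted p = 5.7e-05, and the count of 9345 genes became 5777 without replicate b, 5732 without replicate c and 5272 with slide as a random block. Against the other control set SYNPO2 turned direction, the smooth muscle median was 0.02 and the DNA replication median 0.40, against 1.74 for inflammatory activation.

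Spheres at 73 µg/ml matched the worms in surface area, per the labels, and asked at 4 h what that area does in round form. SELE again led (5.72 ± 0.10), with FOSB (3.73 ± 0.09), ATF3 (3.39 ± 0.07), the drug efflux pump ABCG2 (3.13 ± 0.08), the leukocyte chemokine CX3CL1 (2.99 ± 0.10), the collagen-crosslinking peroxidase PXDN (2.97 ± 0.08) and the tight junction protein CLDN5 (2.87 ± 0.08). Among those that fell most were the aldehyde oxidase AOX1 (-2.81 ± 0.10) and the serine synthesis enzyme PSAT1 (-2.81 ± 0.15). Of the inflammatory activation genes 21 of 26 rose, 1 fell and 4 did not pass (22 rose and 1 fell adjusted over the list alone). Their median was 1.65 (adjusted p = 1.8e-20). Of the immediate early genes 14 of 20 rose, 2 fell and 4 did not pass (15 rose and 2 fell adjusted over the list alone). Their median was 0.80 (adjusted p = 7.0e-11). Mitosis genes were lower, as 30 of 30 fell (30 fell adjusted over the list alone), with CDK1, the kinase that starts mitosis, at -1.68 ± 0.07. Mitosis had a median of -1.12 (adjusted p = 3.0e-31). Of the DNA replication genes 30 of 30 fell (30 fell adjusted over the list alone), with the replisome gene GINS2 at -2.15 ± 0.07. DNA replication had a median of -1.05 (adjusted p = 1.5e-31). Of the cholesterol synthesis genes 22 of 23 fell and 1 did not pass (23 fell adjusted over the list alone). Their median was -1.14 (adjusted p = 1.9e-23). Of the metallothioneins 9 of 10 fell and 1 rose (9 fell and 1 rose adjusted over the list alone). Their median was -1.67 (adjusted p = 4.3e-08, adjusted p = 0.067 with an estimated correlation). Notch and angiogenesis genes were higher, in that 16 of 19 rose, 2 fell and 1 did not pass (16 rose and 2 fell adjusted over the list alone). Their median was 0.83 (adjusted p = 1.1e-10). Of the extracellular matrix genes 17 of 24 rose, 2 fell and 5 did not pass (17 rose and 2 fell adjusted over the list alone). Their median was 0.63 (adjusted p = 1.3e-08). Markers of other cells moved alongside, since of the fibroblast markers 5 of 9 rose and 4 did not pass (6 rose adjusted over the list alone) and of the lymphatic endothelial markers 3 of 4 rose and 1 did not pass (3 rose adjusted over the list alone). Medians were 0.56 for fibroblast markers (adjusted p = 5.2e-04) and 0.75 for lymphatic endothelial markers (adjusted p = 0.0032). The second control set minus the first stood at -2.56 for PXDN, -1.84 for CLDN5 and -1.80 for ABCG2, and against the other set the Notch median was 0.21, that of extracellular matrix 0.12 and that of fibroblast markers -0.04, while those of mitosis (-1.99), cholesterol synthesis (-1.02) and inflammatory activation (0.86) kept their sign. Named genes were past adjusted p = 1.0e-12 in limma, and 5659 genes changed with slide as a random block.

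At 24 h the same spheres asked how the response to that surface area developed. SELE (5.42 ± 0.10), RRAD (5.23 ± 0.10), CCL20 (4.89 ± 0.07) and BIRC3 (4.22 ± 0.08) rose, together with the chaperones DNAJA4 (4.75 ± 0.10) and HSPA6 (4.26 ± 0.07). The thiolase ACAT2 (-2.29 ± 0.07), the G-protein regulator RGS5 (-2.23 ± 0.07) and the sterol enzyme MSMO1 (-2.05 ± 0.08) were among those that fell most. Of the inflammatory activation genes 25 of 26 rose and 1 did not pass (25 rose adjusted over the list alone). Their median was 2.38 (adjusted p = 9.9e-28). Of the interferon response genes 20 of 26 rose, 2 fell and 4 did not pass (20 rose and 2 fell adjusted over the list alone). Their median was 0.42 (adjusted p = 8.7e-07). The heat shock list was mixed, as 7 of 14 rose, 2 fell and 5 did not pass (8 rose and 2 fell adjusted over the list alone), with the inducible chaperone HSPA1A at 2.09 ± 0.11. The heat shock median was 0.18 (adjusted p = 0.0031, adjusted p = 0.051 with an estimated correlation). Cholesterol synthesis genes were low here too, and 22 of 23 fell and 1 did not pass (23 fell adjusted over the list alone). Their median was -1.12 (adjusted p = 1.7e-21). For mitosis 30 of 30 fell (30 fell adjusted over the list alone). Their median was -0.78 (adjusted p = 4.1e-23). For DNA replication 28 of 30 fell, 1 rose and 1 did not pass (29 fell and 1 rose adjusted over the list alone). Their median was -0.86 (adjusted p = 1.7e-22). Of the Notch and angiogenesis genes 17 of 19 rose and 2 did not pass (17 rose and 1 fell adjusted over the list alone), with the transcription factor HEY1 at 2.43 ± 0.10. The Notch and angiogenesis median was 1.03 (adjusted p = 2.0e-12). Markers of smooth muscle moved with them, as 4 of 8 rose and 4 did not pass (4 rose adjusted over the list alone), mainly through the actin-binding CNN1 (2.08 ± 0.14). Smooth muscle markers had a median of 0.17 (adjusted p = 0.027, adjusted p = 0.074 with an estimated correlation). For named genes the limma adjusted p was at most 3.4e-11. Against the other control set the Notch median was 0.63 and the interferon median 0.18, and CNN1 (0.15) was not past the test.

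G3.5-COOH carries negative surface groups, and the question was what it alters in the cells. Changes of at least 2-fold numbered 0 higher and 0 lower genes at 4 h and 0 and 2 at 24 h. The collagenase MMP1 rose by 0.80 ± 0.09 at 4 h and 0.99 ± 0.09 at 24 h, the ribosomal protein RPS2 by 0.69 ± 0.08 and 0.91 ± 0.08, and the zinc exporter SLC30A1 by 0.71 ± 0.10 at 4 h (0.43 without replicate a). KHDC4 (-0.89 ± 0.08) and BANP (-0.83 ± 0.07) fell at 4 h, and PI16 (-1.65 ± 0.16), the prostaglandin transporter SLCO2A1 (-0.70 ± 0.09) and CX3CL1 (-0.70 ± 0.10) at 24 h. Of the ribosomal proteins 21 of 36 rose and 15 did not pass (29 rose adjusted over the list alone) at 4 h and 26 of 36 rose and 10 did not pass (31 rose adjusted over the list alone) at 24 h. Medians for ribosomal proteins were 0.29 (adjusted p = 4.8e-24) and 0.36 (adjusted p = 9.6e-41). Of the TGF-beta and BMP response genes 3 of 15 rose and 12 did not pass (4 rose adjusted over the list alone) at 4 h. The TGF-beta and BMP response median was 0.16 (adjusted p = 0.0032). Integrated stress response genes at 4 h were lower by list, and 7 of 24 fell and 17 did not pass (10 fell and 1 rose adjusted over the list alone), their median turning to 0.40 when each array was centred on its median. Their median was -0.14 (adjusted p = 3.3e-06, adjusted p = 0.14 with an estimated correlation), and -0.06 without 4 h replicate a and -0.24 without 4 h replicate b. Of the endothelial identity genes at 24 h 3 of 26 fell and 23 did not pass (6 fell and 1 rose adjusted over the list alone), their median turning to 0.15 when each array was centred on its median. Their median was -0.12 (adjusted p = 4.4e-04). MMP1 and RPS2 were higher in all 9 groups, as were 14 ribosomal proteins in all. Measured against the mean of the other 8 groups MMP1 and RPS2 at 4 h and MMP1 at 24 h turned direction, and RPS2 at 24 h and SLC30A1 were not past the test, nor were BANP with median centring (-0.09) and PI16 against the other control set (-0.04). In limma the adjusted p was at most 1.7e-04 and 4.2e-04 for the named genes. The 1610 genes at 4 h became 660 without replicate a, 453 without replicate c and 364 with slide as a random block, and the 761 at 24 h became 199, 228 and 274 without replicates a, b and c and 30 with the block, SLCO2A1 and CX3CL1 not among them.

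G4-NH2 carries positive surface groups, and the same question was asked of it. At 4 h the testis antigen CTAG1A rose by 3.63 ± 0.21, the neuronal adhesion gene SLITRK4 by 3.49 ± 0.06, PXDN by 3.31 ± 0.08 and CLDN5 by 3.07 ± 0.08, and at 24 h they stood at 3.73 ± 0.21, 3.43 ± 0.06, 3.21 ± 0.08 and 3.02 ± 0.08. In these genes the second control set minus the first stood at -2.52, -2.97, -2.56 and -1.84. PCK2, a mitochondrial enzyme of glucose synthesis, fell by 2.16 ± 0.12 at 4 h and 2.10 ± 0.12 at 24 h, and the asparagine synthetase ASNS was at -1.74 ± 0.13 and -1.62 ± 0.13. Of the cholesterol synthesis genes 22 of 23 fell and 1 did not pass (22 fell adjusted over the list alone) at 4 h and 22 of 23 fell and 1 did not pass (22 fell adjusted over the list alone) at 24 h. For cholesterol synthesis the medians were -0.89 (adjusted p = 8.4e-24) and -0.86 (adjusted p = 2.0e-22). The integrated stress response list fell as well, and 20 of 24 fell, 1 rose and 3 did not pass (21 fell and 1 rose adjusted over the list alone) at 4 h and 19 of 24 fell, 1 rose and 4 did not pass (20 fell and 1 rose adjusted over the list alone) at 24 h. Medians for integrated stress response were -0.58 (adjusted p = 7.6e-13) and -0.60 (adjusted p = 5.4e-12). Of the Notch and angiogenesis genes 13 of 19 rose and 6 did not pass (14 rose adjusted over the list alone) at 4 h and 11 of 19 rose, 2 fell and 6 did not pass (12 rose and 2 fell adjusted over the list alone) at 24 h. For Notch and angiogenesis the medians were 0.78 (adjusted p = 2.7e-12) and 0.63 (adjusted p = 3.6e-08). Mitosis genes were higher, in that 23 of 30 rose and 7 did not pass (23 rose adjusted over the list alone) at 4 h and 30 of 30 rose (30 rose adjusted over the list alone) at 24 h. Medians for mitosis were 0.34 (adjusted p = 8.1e-11, adjusted p = 0.14 with an estimated correlation) and 0.71 (adjusted p = 6.3e-24). Of the DNA replication genes 19 of 30 fell, 1 rose and 10 did not pass (22 fell and 1 rose adjusted over the list alone) at 4 h. For DNA replication the median was -0.23 (adjusted p = 8.5e-08, adjusted p = 0.18 with an estimated correlation). Against the other control set the mitosis medians were -0.53 and -0.20 and the Notch medians 0.17 and 0.04, while cholesterol synthesis stayed at -0.58 and -0.52. Named genes were past adjusted p = 2.7e-10 and 8.1e-10 in limma, and 3845 genes changed at 4 h with slide as a random block.

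**Figure D2:**
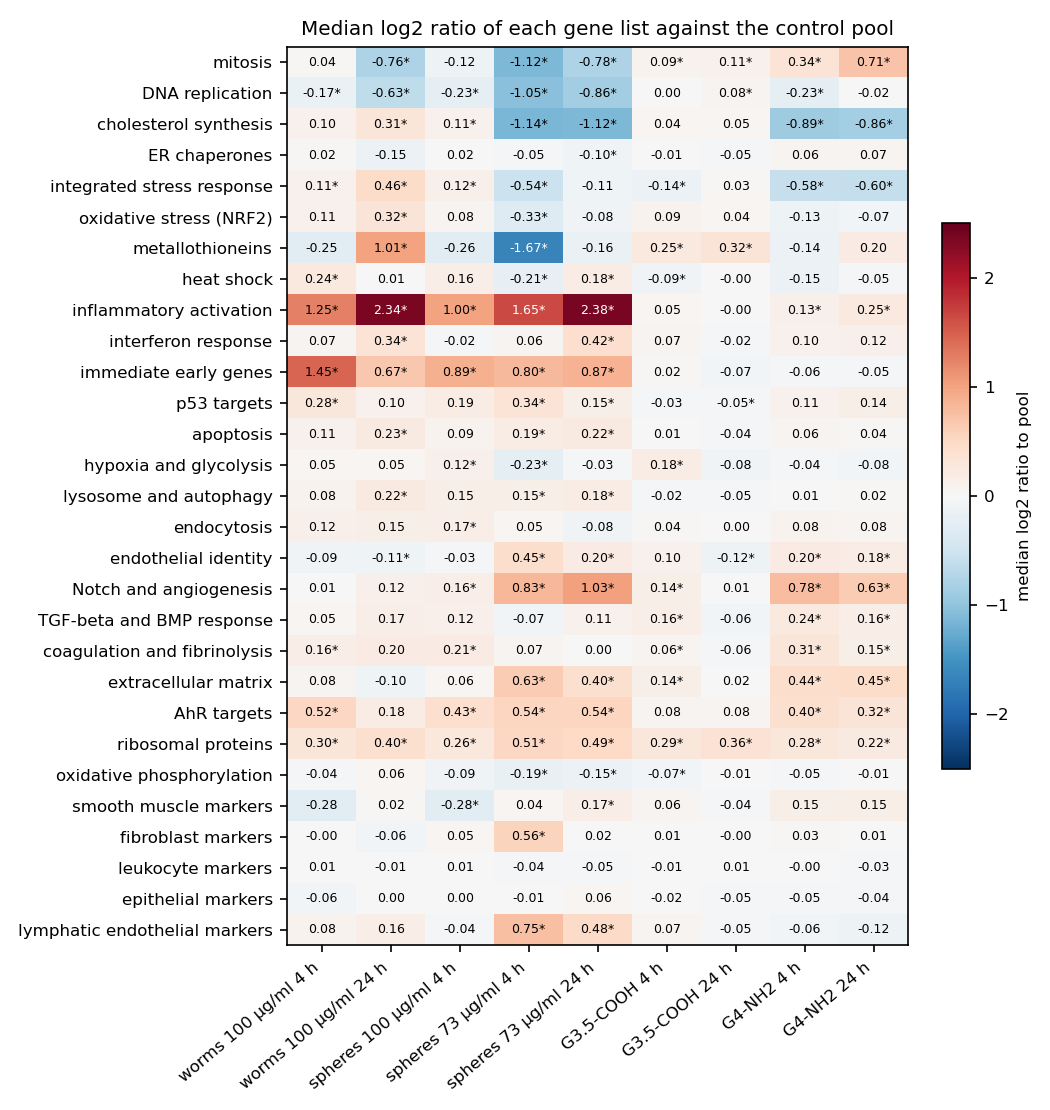
Median log2 ratio of each gene list in the 9 groups against the control pool, with an asterisk where the camera adjusted p is below 0.05. Inflammatory activation ran from 1.0 to 2.38 across the silica groups, and centring each array on its median turned 29 of the 256 list medians past the test over all comparisons.

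Worms and spheres at equal mass for 4 h asked about elongated shape, with all worm arrays on 1 slide and all sphere arrays on another, so that slide is told from shape only by 1 worm array of 24 h on each. The immediate early genes FOS (1.19 ± 0.12), EGR1 (1.06 ± 0.11) and ZFP36 (0.80 ± 0.12), the last an mRNA-destabilizing protein, and the chemokine CXCL2 (1.04 ± 0.12) were higher with worms, as was ATF3 (0.88 ± 0.10). Of the immediate early genes 6 of 20 were higher and 14 did not pass (10 higher adjusted over the list alone). Their median was 0.36 (adjusted p = 3.0e-21), and 0.56 with slide as a fixed block, which rests on these arrays. Of the inflammatory activation genes 2 of 26 were higher and 24 did not pass (8 higher adjusted over the list alone). Their median was 0.16 (adjusted p = 1.9e-07, adjusted p = 0.17 with an estimated correlation), and 0.25 under the slide block, and 0.25 without sphere replicate b and 0.11 without sphere replicate c. SPSB1, which marks proteins for degradation, was lower with worms (-0.54 ± 0.08). In all 46 genes differed (35 higher and 11 lower, adjusted p at most 0.0044 for those named, limma), and for the 24407 others the median half-width of the 95% interval was 0.17. The count became 16 without worm replicate a, 75 without sphere replicate a, 19 without sphere replicate c, 7 with slide as a random block, 498 without both arrays that stand apart, 179 with slide as a fixed block, 1 with median centring and 1 from the 6 arrays alone. Of the genes named, FOS alone stayed past the test with median centring and EGR1 alone from the 6 arrays, while ATF3 and CXCL2 were not past it with the fixed block, nor ZFP36 and SPSB1 with the random block.

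At equal surface area and 4 h the contrast of worms with spheres asked the same of shape, but the 2 groups lie in different control sets. Cholesterol synthesis genes were higher with worms, in that 23 of 23 were higher (23 higher adjusted over the list alone). Their median was 1.24 (adjusted p = 3.3e-22). Mitosis genes differed alike, as 30 of 30 were higher (30 higher adjusted over the list alone), with CDCA8, a subunit of the chromosomal passenger complex, at 2.65 ± 0.09 and CDK1 at 1.89 ± 0.09. The mitosis median difference was 1.14 (adjusted p = 5.5e-27). For DNA replication 29 of 30 were higher and 1 did not pass (29 higher adjusted over the list alone). Their median was 0.98 (adjusted p = 2.4e-24). For the integrated stress response 21 of 24 were higher, 1 lower and 2 did not pass (21 higher and 1 lower adjusted over the list alone), with PSAT1 at 2.87 ± 0.22. The integrated stress response median difference was 0.92 (adjusted p = 1.5e-10). PXDN (-3.31 ± 0.12), the fatty acid carrier FABP4 (-3.17 ± 0.30) and CLDN5 (-2.65 ± 0.11) were lower with worms. Of the Notch and angiogenesis genes 15 of 19 were lower, 2 higher and 2 did not pass (15 lower and 2 higher adjusted over the list alone). Their median was -0.83 (adjusted p = 1.1e-06). Of the extracellular matrix genes 18 of 24 were lower, 2 higher and 4 did not pass (18 lower and 2 higher adjusted over the list alone). Their median was -0.60 (adjusted p = 1.2e-05). Fibroblast markers went with them, as 8 of 9 were lower and 1 did not pass (8 lower adjusted over the list alone). Their median was -0.45 (adjusted p = 0.0011). From the treated channel alone the median differences were 1.03 for cholesterol synthesis, 2.10 for mitosis, 1.56 for DNA replication, 0.39 for the integrated stress response, -0.25 for Notch and angiogenesis, -0.04 for extracellular matrix and 0.12 for fibroblast markers. In limma 9829 genes differed (4590 higher and 5239 lower, adjusted p at most 1.9e-08 for those named) and 6114 with slide as a random block. By the treated channel alone the balance turned to 8166 higher and 6311 lower, as with median centring (4503 and 2119), with 5125 calls kept and 1380 turned in direction.

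The same contrast at 24 h asked whether shape mattered after a day, again across the control sets. The sterol genes ACAT2 (2.66 ± 0.10), INSIG1 (2.63 ± 0.21) and MSMO1 (2.58 ± 0.12) and the fatty acid desaturase FADS2 (2.71 ± 0.12) were higher with worms. Of the cholesterol synthesis genes 22 of 23 were higher and 1 did not pass (22 higher adjusted over the list alone). Their median was 1.46 (adjusted p = 1.2e-33). HSPA6 (-2.71 ± 0.10), DNAJA4 (-2.69 ± 0.14), ABCG2 (-3.01 ± 0.11) and CLDN5 (-2.57 ± 0.11) were lower with worms. Of the heat shock genes 6 of 14 were lower and 8 did not pass (6 lower adjusted over the list alone), their median turning to 0.07 when each array was centred on its median. Their median was -0.19 (adjusted p = 0.0046, adjusted p = 0.099 with an estimated correlation). Of the Notch and angiogenesis genes 15 of 19 were lower and 4 did not pass (15 lower and 1 higher adjusted over the list alone). Their median was -0.86 (adjusted p = 4.4e-10). Of the endothelial identity genes 15 of 26 were lower, 3 higher and 8 did not pass (15 lower and 3 higher adjusted over the list alone). Their median was -0.37 (adjusted p = 1.4e-05). Smooth muscle markers were lower, as 5 of 8 were lower and 3 did not pass (5 lower adjusted over the list alone), with CNN1 at -2.32 ± 0.20. The smooth muscle marker median difference was -0.26 (adjusted p = 0.024, adjusted p = 0.099 with an estimated correlation). From the treated channel alone the median difference was 1.33 for cholesterol synthesis, -0.35 for heat shock, -0.14 for Notch and angiogenesis and 0.07 for smooth muscle markers, with CNN1 not past the test (-0.39). In limma 7615 genes differed (3272 higher and 4343 lower, adjusted p at most 9.9e-09 for those named), 2303 with median centring and 14155 with scan run as a covariate, a fit that rests on 1 worm array at 24 h. The treated channel alone turned the balance to 7275 higher and 4942 lower, with 1809 calls kept and 2247 turned in direction.

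Spheres at 100 µg/ml against 73 µg/ml at 4 h asked for an effect of dose, and this contrast crosses the control sets too. PSAT1 (2.88 ± 0.22), AOX1 (2.85 ± 0.14) and the lactate exporter SLC16A3 (2.28 ± 0.30) were higher at 100 µg/ml, and ABCG2 (-3.15 ± 0.11), PXDN (-3.15 ± 0.12), FABP4 (-3.02 ± 0.30) and CLDN5 (-2.76 ± 0.11) lower. Of the cholesterol synthesis genes 23 of 23 were higher (23 higher adjusted over the list alone). Their median was 1.31 (adjusted p = 5.0e-25). Of the mitosis genes 30 of 30 were higher (30 higher adjusted over the list alone). Their median was 1.02 (adjusted p = 8.8e-27). For hypoxia and glycolysis 14 of 21 were higher, 1 lower and 6 did not pass (14 higher and 1 lower adjusted over the list alone). Their median was 0.66 (adjusted p = 8.4e-06). Inflammatory activation genes were lower at the higher dose, as 13 of 26 were lower, 1 higher and 12 did not pass (13 lower and 1 higher adjusted over the list alone), with CX3CL1 at -2.06 ± 0.15 and SELE at -1.46 ± 0.14. The inflammatory activation median difference was -0.25 (adjusted p = 4.6e-04, adjusted p = 0.13 with an estimated correlation), and -0.40 without sphere replicate b and -0.15 without sphere replicate c. Notch and angiogenesis genes were lower too, and 15 of 19 were lower, 2 higher and 2 did not pass (15 lower and 2 higher adjusted over the list alone). Their median was -0.66 (adjusted p = 1.5e-06). Of the fibroblast markers 6 of 9 were lower and 3 did not pass (7 lower adjusted over the list alone). Their median was -0.50 (adjusted p = 0.0015). From the treated channel alone the median differences were 1.04 for cholesterol synthesis, 1.98 for mitosis, 0.06 for inflammatory activation, -0.10 for Notch and angiogenesis and 0.11 for fibroblast markers. By limma 8894 genes differed (4168 higher and 4726 lower, adjusted p at most 2.9e-06 for those named), and 4680 with slide as a random block. In the treated channel alone 8613 were higher and 6285 lower, so that the balance turned, as it did with median centring (3782 and 1832), with 4674 calls kept and 1314 turned in direction.

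The dendrimers differ in surface charge, negative carboxylates on G3.5-COOH and positive amines on G4-NH2, and were compared at the same dose and time within 1 control set but on different slides, so that charge and slide cannot be separated. With G4-NH2 the genes SLITRK4 (3.53 ± 0.08 at 4 h and 3.29 ± 0.08 at 24 h), PXDN (3.21 ± 0.12 and 3.07 ± 0.12), CLDN5 (3.16 ± 0.11 and 3.27 ± 0.11) and SERPINB2, an inhibitor of plasminogen activators (2.88 ± 0.13 and 2.79 ± 0.13), were higher than with G3.5-COOH. SLITRK4, PXDN, CLDN5 and SERPINB2 differed between the control sets too, by -2.97, -2.56, -1.84 and -2.23 for the second set minus the first. Lower were the sterol enzyme HMGCS1 (-1.75 ± 0.32 and -1.63 ± 0.32), MSMO1 (-1.73 ± 0.12) at 4 h, and PCK2 (-2.08 ± 0.17) and COX1 (-2.97 ± 0.35) at 24 h. Of the cholesterol synthesis genes 20 of 23 were lower and 3 did not pass (22 lower adjusted over the list alone) at 4 h and 21 of 23 were lower and 2 did not pass (22 lower adjusted over the list alone) at 24 h. For cholesterol synthesis the medians were -0.94 (adjusted p = 2.9e-33) and -0.91 (adjusted p = 2.3e-28). The integrated stress response was lower with G4-NH2, as 14 of 24 were lower and 10 did not pass (15 lower adjusted over the list alone) at 4 h and 18 of 24 were lower, 1 higher and 5 did not pass (18 lower and 1 higher adjusted over the list alone) at 24 h. Medians for integrated stress response were -0.40 (adjusted p = 1.0e-10) and -0.53 (adjusted p = 1.9e-14). Of the Notch and angiogenesis genes 12 of 19 were higher and 7 did not pass (12 higher adjusted over the list alone) at 4 h and 13 of 19 were higher, 1 lower and 5 did not pass (13 higher and 1 lower adjusted over the list alone) at 24 h. For Notch and angiogenesis the medians were 0.70 (adjusted p = 8.4e-15) and 0.74 (adjusted p = 1.2e-12). Mitosis genes were higher at 24 h, in that 25 of 30 were higher and 5 did not pass (29 higher adjusted over the list alone), and at 4 h 13 of 30 were higher and 17 did not pass (19 higher adjusted over the list alone), their median turning to -0.08 when each array was centred on its median. Medians for mitosis were 0.55 (adjusted p = 1.6e-22) and 0.25 (adjusted p = 1.3e-09, adjusted p = 0.16 with an estimated correlation). Of the smooth muscle markers at 24 h 2 of 8 were higher and 6 did not pass (2 higher adjusted over the list alone), namely ACTA2 (0.93 ± 0.07) and TAGLN (0.60 ± 0.11). Smooth muscle markers had a median difference of 0.07 (adjusted p = 0.035, adjusted p = 0.12 with an estimated correlation), and 0.11 without G4-NH2 replicate b and 0.04 without G4-NH2 replicate c. In limma 3016 genes differed at 4 h and 3719 at 24 h (adjusted p at most 4.0e-04 and 7.5e-04 for those named), 6352 and 7325 without both arrays that stand apart, and 1308 and 2030 with slide as a random block, where HMGCS1 at 24 h (-1.15) was not past the test, nor TAGLN with median centring (0.64). For the 21437 and 20734 genes with no detected difference the 95% interval had a median half-width of 0.18 at both times and excluded a 2-fold difference for 99.1% and 99.1% of them.

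Change over time with worms, 24 h minus 4 h, asked which responses are early and which late. TNF (2.69 ± 0.06), the lymphotoxin LTB (2.48 ± 0.08), UBD (2.44 ± 0.13), CCL20 (2.34 ± 0.11) and the histone genes H2AC8 (3.26 ± 0.09) and H1-2 (2.52 ± 0.13) were higher at 24 h, and the shear-responsive transcription factor KLF2 (-2.34 ± 0.30) and FOS (-1.92 ± 0.12) lower. Of the immediate early genes 14 of 20 were lower, 1 higher and 5 did not pass (16 lower and 1 higher adjusted over the list alone). Their median was -0.80 (adjusted p = 4.0e-11), and -0.74 within the slide that holds both groups, where each such value rests on 1 array at 24 h. For inflammatory activation 18 of 26 were higher, 2 lower and 6 did not pass (18 higher and 2 lower adjusted over the list alone). Their median was 0.80 (adjusted p = 9.3e-09, adjusted p = 0.053 with an estimated correlation), and 0.77 within the slide. Mitosis genes were lower at 24 h, as 29 of 30 were lower and 1 did not pass (30 lower adjusted over the list alone). Their median was -0.91 (adjusted p = 4.0e-27), and -0.72 within the slide. Of the DNA replication genes 25 of 30 were lower, 1 higher and 4 did not pass (25 lower and 1 higher adjusted over the list alone). Their median was -0.49 (adjusted p = 5.8e-13, adjusted p = 0.075 with an estimated correlation), and -0.32 within the slide. Metallothioneins were higher, and 9 of 10 were higher and 1 did not pass (9 higher adjusted over the list alone). Their median was 1.22 (adjusted p = 5.3e-08, adjusted p = 0.099 with an estimated correlation), and 0.96 within the slide. The 24 h group holds 1 array that stands apart, and without replicate c the medians were -0.75 for immediate early genes, 0.77 for inflammatory activation, -0.77 for mitosis, -0.34 for DNA replication and 0.95 for metallothioneins. By limma 7944 genes differed (4295 higher and 3649 lower, adjusted p at most 5.2e-06 for those named), 6561 within the slide, 2345 with median centring (1162 and 1183) and 874 from the 6 arrays alone, KLF2 not among them. On the authors' processed signals CCL20 was not past the test (1.02).

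Over time with 73 µg/ml spheres the chaperones HSPA6 (4.67 ± 0.10) and DNAJA4 (3.89 ± 0.14), the histone genes H2AC8 (3.80 ± 0.09) and H2BC8 (3.57 ± 0.12), CCL20 (3.23 ± 0.10) and RRAD (3.08 ± 0.14) were higher at 24 h. The metabolic kinase PDK4 (-1.40 ± 0.16), SLCO2A1 (-1.31 ± 0.13), the monoamine oxidase MAOA (-1.25 ± 0.08) and KLF2 (-1.22 ± 0.30) were lower. Of the heat shock genes 8 of 14 were higher, 1 lower and 5 did not pass (9 higher and 1 lower adjusted over the list alone). Their median was 0.43 (adjusted p = 5.0e-09), and 0.31 within the slide that holds both groups, where each such value rests on 1 array at 24 h. For metallothioneins 8 of 10 were higher and 2 did not pass (9 higher adjusted over the list alone). Their median was 1.46 (adjusted p = 5.9e-11), and 1.49 within the slide. Integrated stress response genes were higher, as 17 of 24 were higher and 7 did not pass (20 higher adjusted over the list alone). Their median was 0.54 (adjusted p = 1.7e-12), and 0.50 within the slide. Of the interferon response genes 15 of 26 were higher, 1 lower and 10 did not pass (17 higher and 1 lower adjusted over the list alone). Their median was 0.33 (adjusted p = 3.7e-08), and 0.40 within the slide. Inflammatory activation grew, in that 14 of 26 were higher, 1 lower and 11 did not pass (15 higher and 1 lower adjusted over the list alone). Their median was 0.44 (adjusted p = 9.8e-10), and 0.39 within the slide. Of the mitosis genes 16 of 30 were higher and 14 did not pass (20 higher adjusted over the list alone). Their median was 0.32 (adjusted p = 2.6e-10, adjusted p = 0.11 with an estimated correlation), and 0.24 within the slide, and 0.18 without 4 h replicate b. In limma 3575 genes differed (2319 higher and 1256 lower, adjusted p at most 0.0062 for those named), 2912 within the slide, 846 with median centring and 6878 without both arrays that stand apart. CCL20 was not past the test on the authors' processed signals or in their value table (1.45 in both), nor KLF2 with median centring (-1.29).

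Over time few genes passed the test with the dendrimers. With G3.5-COOH KHDC4 (0.82 ± 0.11) and BANP (0.74 ± 0.09) were higher at 24 h, and SLC30A1 (-0.87 ± 0.14) lower. Of the TGF-beta and BMP response genes 2 of 15 were lower and 13 did not pass (2 lower adjusted over the list alone). Their median was -0.24 (adjusted p = 5.3e-06), and -0.20 within the slide. Hypoxia and glycolysis genes were lower by list, although 0 of 21 passed the test over all genes and 9 were lower adjusted over the list alone (median difference -0.23, adjusted p = 6.2e-11). With G4-NH2 the interleukin-33 receptor IL1RL1 (0.61 ± 0.09) and the spindle gene HMMR (0.52 ± 0.09) were higher at 24 h, and LYVE1 (-0.44 ± 0.07), a lymphatic endothelial marker, was lower. Of the mitosis genes 3 of 30 were higher and 27 did not pass (25 higher adjusted over the list alone). Their median was 0.30 (adjusted p = 2.0e-39), and 0.28 within the slide, with 1 array at 24 h. By limma 25 genes differed with G3.5-COOH and 14 with G4-NH2, and for 99.5% and 99.6% of the others the 95% interval excluded a 2-fold difference. The 25 became 12 and 251 without 4 h replicates a and b, 6, 4 and 7 without 24 h replicates a, b and c, 10 with slide as a random block, 109 on the processed signals, 57 from the 6 arrays alone and 748 without both arrays that stand apart. The 14 became 0, 0 and 3 without 4 h replicates a, b and c, 3, 0 and 0 without those of 24 h, 512 from the 6 arrays alone, 321 without both arrays that stand apart and 0 with the block (1432 genes had an unadjusted limma p under 0.05). SLC30A1 was not past the test without 24 h replicates a (-0.88), b (-0.89) and c (-0.85) or with the block (-0.77), and KHDC4 (0.59) and BANP (0.28) with median centring. IL1RL1 (0.56, 0.59, 0.61, 0.57) and LYVE1 (-0.43, -0.41, -0.45, -0.40) were not past it without 4 h replicates a and b or 24 h replicates b and c, in that order, nor HMMR (0.49, 0.47, 0.55, 0.49, 0.51) without those of 4 h or 24 h replicates a, b and c.

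A last pair of tests asked whether shape or charge changed the course over time. Between worms and 73 µg/ml spheres 4009 genes took a different course (1736 higher and 2273 lower for worms), but on the processed signals the balance turned to 2282 and 1897. Median centring left 344 (43 and 301). HSPA6 (-3.16 ± 0.14), HSPA1A (-2.20 ± 0.23) and CDCA8 (-2.23 ± 0.13) rose less or fell more with worms, and TNF (1.39 ± 0.09), CX3CL1 (1.32 ± 0.21) and H1-2 (2.24 ± 0.19) the reverse. Of the mitosis genes 29 of 30 were lower and 1 did not pass (30 lower adjusted over the list alone). Their median was -1.18 (adjusted p = 3.0e-40). Of the DNA replication genes 26 of 30 were lower and 4 did not pass (27 lower adjusted over the list alone). Their median was -0.81 (adjusted p = 6.6e-27). For heat shock 12 of 14 were lower and 2 did not pass (12 lower and 1 higher adjusted over the list alone). Their median was -0.62 (adjusted p = 5.1e-10). For the immediate early genes 7 of 20 were lower and 13 did not pass (7 lower adjusted over the list alone). Their median was -0.36 (adjusted p = 2.2e-05). Each material was measured within its own control set at both times. Between the dendrimers 7 genes differed in course, among them IL1RL1 (0.78 ± 0.13) and KHDC4 (-0.85 ± 0.15). Their TGF-beta and BMP response genes differed as a list, with 0 of 15 past the test over all genes and 3 higher adjusted over the list alone (median 0.19, adjusted p = 2.9e-04). In limma the adjusted p of the named genes was at most 2.1e-04 for shape and 0.04 for charge. The 4009 genes became 2562 and 2577 without worm replicates a and c of 4 h, 6435 without worm replicate c of 24 h, 2634 without sphere replicate b of 24 h, 7631 without both arrays that stand apart and 2396 with slide as a random block. The 7 became 248 without both arrays that stand apart, 312 from the 12 arrays alone, 106 without G3.5-COOH replicate b of 4 h, 2 without G4-NH2 replicate a of 24 h, 1 without G3.5-COOH replicate c of 24 h or G4-NH2 replicate a of 4 h, and 0 without any other replicate but G3.5-COOH replicate c of 4 h, and 0 with the block (1559 genes had an unadjusted limma p under 0.05). KHDC4 was not past the test without any 1 replicate other than replicate b of G3.5-COOH at 4 h (-0.89 to -0.74), nor IL1RL1 without any other than replicates b and c of that group (0.73 to 0.84).

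**Figure D3:**
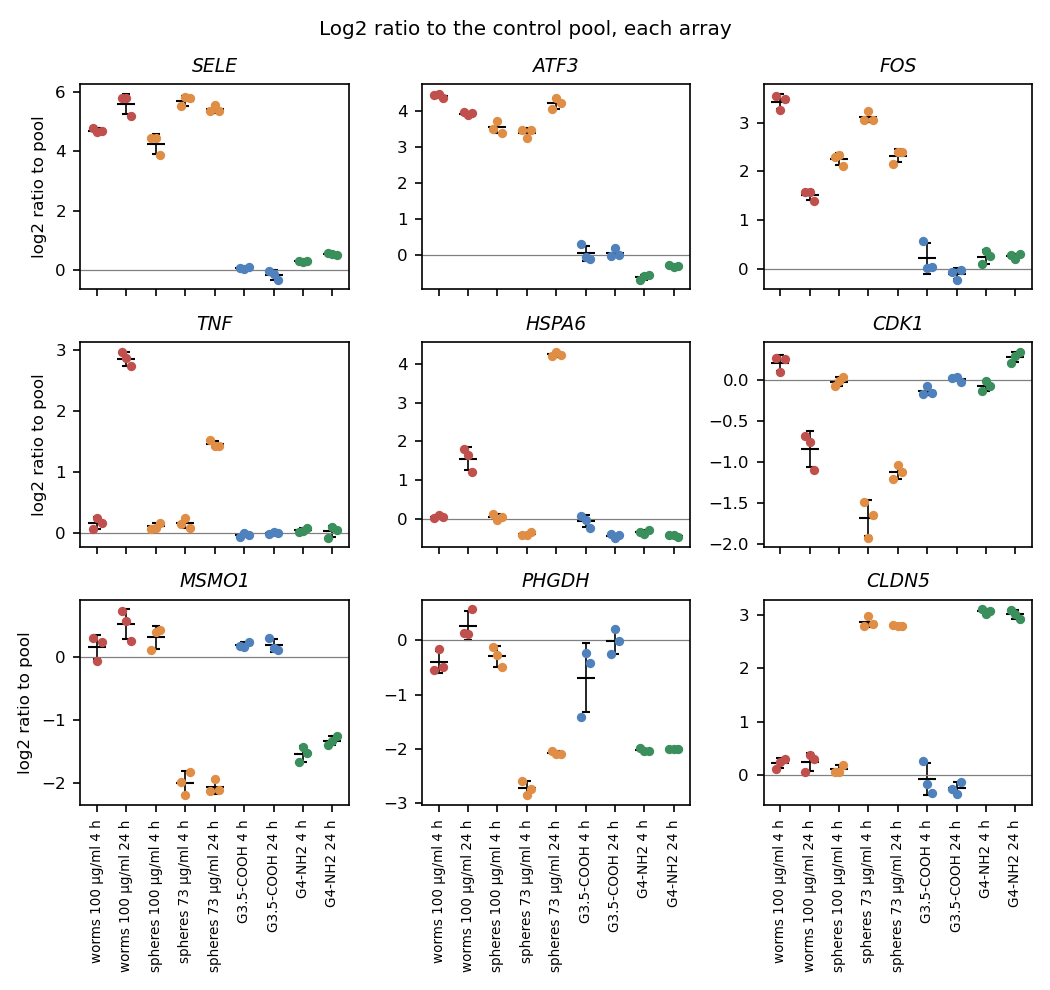
Log2 ratio of 9 genes on each array of the 9 groups, with points for arrays and bars for the mean ± SD (n = 3). SELE lies near 4.70 with worms at 4 h and near 5.42 with 73 µg/ml spheres at 24 h, and HSPA6 at 4.26 in the latter.

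Over the 21 comparisons, the 609 list tests gave 256 past the threshold and 143 with an estimated correlation. Given in turn are the comparisons in which each list was higher, lower, and past the test with an estimated correlation. These were AhR targets (8, 0 and 7), apoptosis (3, 2 and 5), cholesterol synthesis (8, 6 and 10), coagulation and fibrinolysis (7, 1 and 6), DNA replication (9, 10 and 7), endocytosis (2, 0 and 0), endothelial identity (7, 8 and 12), epithelial markers (1, 1 and 0), ER chaperones (0, 2 and 0), extracellular matrix (7, 5 and 9). They were fibroblast markers (1, 3 and 3), heat shock (5, 4 and 3), hypoxia and glycolysis (6, 4 and 2), immediate early genes (7, 4 and 9), inflammatory activation (12, 2 and 6), integrated stress response (9, 8 and 8), interferon response (6, 1 and 3), leukocyte markers (0, 0 and 0), lymphatic endothelial markers (2, 3 and 4), lysosome and autophagy (3, 0 and 3). For the remaining lists they were metallothioneins (10, 2 and 1), mitosis (12, 5 and 10), Notch and angiogenesis (8, 5 and 11), oxidative phosphorylation (3, 3 and 0), oxidative stress (NRF2) (6, 2 and 5), p53 targets (5, 2 and 6), ribosomal proteins (11, 4 and 6), smooth muscle markers (3, 2 and 1), TGF-beta and BMP response (5, 1 and 6). On the authors' processed signals 235 of the tests passed, each in the same direction wherever both did.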

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

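The test of the shift shared by all groups was chosen before its result was seen, and the tests of the other patterns and the counts of other splits in this part were chosen after it.

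Across the 9 groups 87 genes were higher and 13 lower in every one, among them KITLG (mean 1.42), NPTX1 (1.29), MMP1 (1.08), RPL13A (0.79) and 14 ribosomal proteins in all. Noise with no shared pool or dye effect, so testing neither, gave 0 in all 20 simulations with limma. Independent lists would share 1.9e-04 and 4.8e-05 genes. A dye effect or a pool unlike the treated cultures may add such a shift, and on the 1.5 h array the same genes kept 0.695 of their median ratio, with 83 of 87 and 13 of 13 of the same sign. Without a dye swap, a dye effect, the pool and a response common to all materials cannot be told apart, and the last was not tested.

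In 1 array of the worm 24 h group 2399 genes lay at least 2-fold from the control channel. Its difference from the other two arrays of its group correlated across genes, which are not independent replicates, with the difference between the control sets at r = 0.837, so that sets of cells or labelling that differ between its channels may be a source of it. The other arrays of its slide reached at most 0.0186 in size, which argues against the slide. In its scan run 0 other arrays had the first control set, so a scan run effect cannot be told apart from the other explanation. No biological explanation was tested, since the design gives this array the same treatment as the other two.

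With 73 µg/ml spheres and with G4-NH2, 103 genes were at least 2-fold higher at both times, with a median log2 ratio of 1.65. In 99 of them the first control set was higher than the second, and over all 103 the median difference was 1.57, a share of 0.948 of the rise, so control cells or labelling unlike the treated cells before treatment may be a source. These genes were chosen by their ratio to the second set, and over all genes that differ between the sets the same treated channels lay near it, at 0.843 to 0.97, so that this explanation and a response cannot be told apart. A dye or scan run effect was argued against by the G3.5-COOH arrays and the 1.5 h array, of the same dye and scan run, which reached 0.0517 of the rise at most. Among these, 3 lay on slides with 4 of the 12 arrays in question and reached 0.0517 at most, and 2 arrays of the same groups on the slides of the other 8 differed by 0.00974 of the rise at most, with 1 array for each slide, and both values argue against the slide. The 100 µg/ml spheres at 4 h showed 0.0372 of it, but against the first control set, so that this share decides nothing. A response to the spheres or to the amine dendrimer stays open, as untested.

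The course over time differed between materials in 7 genes for charge, a difference between groups tested as an interaction in limma, and 2 of 100 splits gave as many genes, the real one included, with 26 as the highest of the others, several times the real count, which points to a structure of the samples that was not tested. That share does not exclude chance, given the 26. With slide as a random block 0 genes were past the test in limma (1559 had an unadjusted p under 0.05 as reported). Of the 12 fits without 1 replicate 7 gave 0 as well. For shape the course differed in 4009 genes, 2396 with the block. There chance was excluded with the slides set aside, with 1 of 100 splits and 944 as the highest of the others. On the 1.5 h worm array, which no comparison uses, 25 genes lay at least 2-fold above the control channel. On the same array 63 genes lay at least 2-fold below it. For each contrast between 2 groups the 10 splits of the 6 arrays were too few for a share under 0.05, and the real split and the highest of the others gave 46 and 110 for worms against spheres at equal mass, 9829 and 1 for shape at equal area and 4 h, 7615 and 524 for shape at equal area and 24 h, 8894 and 0 for sphere dose, 3016 and 0 for charge at 4 h, 3719 and 0 for charge at 24 h, 7944 and 2904 for time with worms, 3575 and 0 for time with spheres, 25 and 2 for time with G3.5-COOH and 14 and 0 for time with G4-NH2 genes. In the contrast at equal mass 3 splits gave as many genes, the real one included. In each of the other contrasts it was 1, the real split.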

How the results depend on the processing

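The tests that left out a pair of arrays, used the treated channel alone or took the control channel of the other set were chosen after the results were seen, and the cause of each difference in this part was not tested except where it is named. Of the values of named genes under alternatives other than leaving out a replicate, 1852 kept direction and side of the threshold, 65 kept direction but were not past the test and 6 turned direction. Those that turned were MMP1 to -0.314 in G3.5-COOH at 4 h, RPS2 to -0.097 in G3.5-COOH at 4 h and MMP1 to -0.098 in G3.5-COOH at 24 h against the mean of the other 8 groups, NUF2 to 1.104 in worms at 24 h, TK1 to 0.025 in worms at 24 h and SYNPO2 to 0.082 in 100 µg/ml spheres against the other control set. Without 1 replicate 719 kept both and 37 were not past the test.

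Counts of genes that moved by more than 1.5 times were as follows. On the authors' processed signals they were 414 for G3.5-COOH at 24 h, 413 from the authors' own ratios. Both gave 83 for shape at equal mass, 109 for time with G3.5-COOH and 1 for time with G4-NH2. With median centring they were 16222 for worms at 4 h, 15614 for 100 µg/ml spheres, 5168 for 73 µg/ml spheres at 4 h, 5285 for 73 µg/ml spheres at 24 h, 15524 for G3.5-COOH at 4 h, 270 for G3.5-COOH at 24 h, 3126 for G4-NH2 at 4 h, 3717 for G4-NH2 at 24 h, 1 for shape at equal mass, 2303 for shape at equal area at 24 h, 5614 for dose, 1146 for charge at 24 h, 2345 for time with worms, 846 for time with spheres, 1 for time with G3.5-COOH, 0 for time with G4-NH2, 0 for charge by time and 344 for shape by time. Without the background filter 8 for time with G4-NH2 was the count, where 30139 genes were tested. An intensity trend with robust variances gave 15 for time with G3.5-COOH, 4 for time with G4-NH2 and 1 for charge by time. With slide as a random block (correlation 0.477) they were 5272 for 100 µg/ml spheres, 5659 for 73 µg/ml spheres at 4 h, 364 for G3.5-COOH at 4 h, 30 for G3.5-COOH at 24 h, 3845 for G4-NH2 at 4 h, 7 for shape at equal mass, 6114 for shape at equal area at 4 h, 4680 for dose, 1308 for charge at 4 h, 2030 for charge at 24 h, 10 for time with G3.5-COOH, 0 for time with G4-NH2, 0 for charge by time and 2396 for shape by time. The arrays of the groups compared alone, with fewer arrays for the variance, gave 42 for worms at 24 h, 5383 for 100 µg/ml spheres, 5086 for G3.5-COOH at 24 h, 11631 for G4-NH2 at 4 h, 13150 for G4-NH2 at 24 h, 1 for shape at equal mass, 1614 for shape at equal area at 24 h, 5603 for charge at 4 h, 9457 for charge at 24 h, 874 for time with worms, 6577 for time with spheres, 57 for time with G3.5-COOH, 512 for time with G4-NH2, 312 for charge by time and 1432 for shape by time. Against the mean of the other 8 groups they were 2731 for G3.5-COOH at 4 h and 4078 for G3.5-COOH at 24 h. Scan run as a covariate gave 14155 for shape at equal area at 24 h and 6435 for shape by time, the first of which rests on 1 worm array, while the second is the same as leaving out that array. Slide as a fixed block gave 179 for shape at equal mass and 0 for time with G4-NH2, and the slide that holds both groups, with 1 array of one time, 0 for time with G4-NH2. Without both arrays that stand apart, 1 of the worms at 24 h and 1 of the 100 µg/ml spheres, they were 5039 for G3.5-COOH at 4 h, 3708 for G3.5-COOH at 24 h, 11494 for G4-NH2 at 4 h, 11549 for G4-NH2 at 24 h, 498 for shape at equal mass, 6352 for charge at 4 h, 7325 for charge at 24 h, 6878 for time with spheres, 748 for time with G3.5-COOH, 321 for time with G4-NH2, 248 for charge by time and 7631 for shape by time. From the treated channel alone they were 12217 for shape at equal area at 24 h, 14898 for dose, 142 for time with G4-NH2, 17 for charge by time and 2547 for shape by time. Against the other control set they were 18246 for worms at 4 h, 17322 for worms at 24 h, 18330 for 100 µg/ml spheres, 18494 for 73 µg/ml spheres at 4 h, 18680 for 73 µg/ml spheres at 24 h, 18326 for G3.5-COOH at 4 h, 18538 for G3.5-COOH at 24 h, 18395 for G4-NH2 at 4 h and 18281 for G4-NH2 at 24 h. Counts of 0 came from limma, where 1432 genes for time with G4-NH2 and 1559 for charge by time had an unadjusted p under 0.05 in the tests as reported. The gene lists past the test numbered 256 and 143 with an estimated correlation. Aquantile scaling moved no count.

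Leaving out each replicate in turn gave counts for worms at 4 h 7709 to 9738, worms at 24 h 8669 to 11959, 100 µg/ml spheres 5732 to 9546, 73 µg/ml spheres at 4 h 6672 to 7648, 73 µg/ml spheres at 24 h 7928 to 8298, G3.5-COOH at 4 h 453 to 1566, G3.5-COOH at 24 h 199 to 274, G4-NH2 at 4 h 5387 to 5818, G4-NH2 at 24 h 5408 to 5441, shape at equal mass 16 to 75, shape at equal area at 4 h 8297 to 9542, shape at equal area at 24 h 5627 to 10082, dose 7019 to 9438, charge at 4 h 2236 to 2515, charge at 24 h 2843 to 2905, time with worms 5739 to 9294, time with spheres 2545 to 3046, time with G3.5-COOH 4 to 251, time with G4-NH2 0 to 3, charge by time 0 to 106 and shape by time 2562 to 6435. The replicate block gave 5 for time with G4-NH2 and moved no other count by more than 1.5 times. Arrays with the same letter did not deviate together, since in 0 of 36 pairs of groups all letters correlated above 0.1, and 4 of 27 arrays correlated best with their own letter. Where both fits gave at least 40 genes, the share of higher genes moved by more than 10 percentage points as follows, besides the groups with median centring. On the processed signals, and nearly alike from the authors' own ratios, it was 49.7% in place of 62.1% for G3.5-COOH at 4 h, 57.8% in place of 76.1% for shape at equal mass and 54.6% in place of 43.3% for shape by time. With median centring it was 68% in place of 46.7% for shape at equal area at 4 h, 67.4% in place of 46.9% for dose, 68.5% in place of 55.3% for charge at 24 h, 85.2% in place of 64.9% for time with spheres and 12.5% for shape by time. It was 97.6% in place of 50.2% for worms at 24 h, 54.6% in place of 65.8% for G3.5-COOH at 24 h and 28.3% in place of 43% for shape at equal area at 24 h with the arrays of the groups compared alone, 46.8% for G3.5-COOH at 4 h and 49.1% for G3.5-COOH at 24 h against the mean of the other groups, 96.6% for shape at equal mass with slide as a fixed block and 65.1% for shape at equal mass without both arrays that stand apart. The treated channel alone gave 59.5% for shape at equal area at 24 h and 57.8% for dose, and the other control set 43.6% for G3.5-COOH at 4 h and 43.4% for G3.5-COOH at 24 h. Leaving out 1 replicate gave 91.1% for shape at equal mass without worm replicate c, 54.7% for shape at equal mass without sphere replicate a, 77.1% for G3.5-COOH at 4 h without replicate a and 47.2% for G3.5-COOH at 4 h without replicate b. Against the other control set more calls turned direction than were kept for worms at 24 h alone (4537 and 3600). The signal limits what was tested, as 71.1% to 81.5% of probes lay well above background in the treated channel, and a gene under that level in all groups was not tested.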

Other observations

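After 1.5 h with worms, on 1 array with no replicate check, the genes farthest above the control channel were SELE (3.28), the synaptic protein NPTX1 (3.20), SLC39A7 (1.75), CYP1B1 (1.74), FGFR3 (1.69) and the monocyte chemokine CCL2 (1.58), followed further down by FOSB (1.37) and HMOX1 (1.19). Farthest below were the mitochondrial COX1 (-2.05), the activin subunit INHBB (-2.01), PI16 (-1.83), CYTB (-1.77) and the stem cell factor receptor KIT (-1.68), with the angiogenic growth factor VEGFA (-1.42) among the others. These genes were chosen after their values were seen. The array carries the second control set, and that set minus the first stood in these genes, in this order, at -1.36, -1.41, -1.08, -1.63, -0.80, -0.92, -0.45, -0.59, 1.50, -0.65, 1.6, 0.49, -0.59 and 1.38, opposite in sign to the ratio in all but INHBB and KIT. Of the gene lists, placed among 10000 random lists of the same size and intensity, AhR targets (median 0.50), metallothioneins (0.40), ribosomal proteins (0.22), cholesterol synthesis (0.20), mitosis (0.19), inflammatory activation (0.18) and NRF2 targets (0.16) lay high, at percentile 100 after rounding. Hypoxia and glycolysis (median -0.54, percentile 0), the integrated stress response (median -0.52, percentile 0), endothelial identity (median -0.17, percentile 0.11), ER chaperones (median -0.17, percentile 0.29) and heat shock (median -0.19, percentile 0.34) lay low, and the other lists between percentiles 1.42 and 91.6. The percentiles describe this array alone.

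Some gene lists had calls not described above, 1 of which is given here from the same limma and camera tests. With 73 µg/ml spheres at 4 h, 15 of 23 rose and 8 did not pass (15 rose adjusted over the list alone) among the p53 targets, and against the other control set their median was 0.01. The p53 target median was 0.34 (adjusted p = 5.7e-05). No hypothesis beyond those already weighed was tested.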
